A study of Mus musculus with 23 samples.

How the data were processed

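Poly(A) RNA was sequenced from 23 samples in 8 groups, 14 from culture and 9 from animals, with directional libraries on a HiSeq2000. Of the groups, 7 had 3 samples and 1 had 2. Per the submitters' processing notes, TopHat2, Bowtie2, Cufflinks and Cuffdiff 2.2.1 were used with the mouse genome mm10. The processed file was a table of 22784 gene symbols with 8 columns, and the unit deposited by the authors is FPKM, with 1 value per gene and group. Raw reads were not analysed here.

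The plan made before the data were examined assumed values per sample, with limma and camera tests. The table holds 1 value per group instead, so the fallback of that plan was used, in which genes are ranked by log2 ratio without a test. No p-value, standard error or replicate spread is given anywhere. The few intervals given are over genes taken as independent, and do not measure the spread between samples. Read depth is not given in the sources used here, and cannot be recovered from the table. Its lowest values above 0 are far below what 1 read would give in a normal library, for example 7.6e-06 FPKM for Eno1 in in vitro MII oocytes.

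Values were taken as log2(FPKM + 1). A gene was tested where it had at least 1 FPKM in at least 1 of the 8 groups, which left 14242 genes, and this replaced a filter of 2 or more samples that needs values per sample. A gene was called higher or lower where the difference of log2 values was at least 1, that is 2-fold. The 11 comparisons were 3 of culture against animal at the same stage, 6 of consecutive stages, and 2 of a step in culture against the same step in the animal, as a difference of log2 ratios. Agreement of 2 steps was given as the number of genes called the same way in both, beside the number for independent lists with the same counts.

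The 29 gene lists were fixed beforehand from background knowledge, and 28 had at least 4 measured members. The list of Y-linked genes had 0. Of 603 symbols asked for, 592 were found as written, 5 by an older symbol and 6 not. For each list the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression, and by chance 5% of lists fall outside the central 95%. Matching on expression does not remove shared regulation within a list, so percentiles rank lists and are not tests.

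Genes named by rank had at least 10 FPKM in the higher group and a symbol that is not a predicted or clone name. They were the 8 highest and 8 lowest by log2 ratio in the first 7 comparisons, and the 6 highest and 6 lowest in the step differences. From each list up to 4 called members with the largest ratio were eligible to be named. Reported in any case were Nanog, Pou5f1, Dppa3, Ddx4, Dazl, Stra8, Sycp3, Figla, Nobox, Gdf9, Bmp15, Zp3, Nlrp5, Mos, Amh and Foxl2. The plan also asked that replicates not overlap, which could not be applied. Other genes in the text were chosen after their values were seen. Coordinates are those of GENCODE release M21 for GRCm38.

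Alternatives planned beforehand and run were a pseudocount of 0.1 or 5, a filter of 5 FPKM or none, quantile normalization and centring on the median. Centring was applied after the pseudocount and the log, so it shifts all log2 ratios of a comparison by the same constant, those of genes at 0 FPKM included. Those chosen after the data were seen were scaling to equal sums, no pseudocount over genes with at least 1 FPKM in the groups compared, counts without ribosomal and respiratory chain genes, and similarity over genes with at least 1 FPKM in all 8 groups.

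The steps were tested on simulated data made from the in vivo secondary follicle values with noise of 0.275 log2 units. Of 100 genes changed 3-fold, 98 were recovered, and of 100 changed 8-fold, 100. Of 14042 unchanged genes, 0 were called. Of 200 random lists of 20 genes, 12 (6%) fell outside the central 95%, and a list made higher came out above all 10000 random lists. The noise was taken from the median absolute deviation of log2 ratios between the secondary follicle groups across genes, which sets aside extreme ratios. It is not a measure of the spread between samples, and the changed genes had at least 10 FPKM. The standard deviation of these ratios was 0.381, and 0.864 for the MII oocytes. With noise this small, the absence of calls among unchanged genes was largely fixed in advance. So were the recovery of changed genes and the place of the list made higher, whose genes were all raised 3-fold. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, with random draws from seed 7.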

Results

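The data cover the making of mouse oocytes in culture and in the animal, by poly(A) RNA sequencing of 23 samples in 8 groups. The culture route began with female embryonic stem (ES) cells. It went on to primordial germ cell-like cells (PGCLCs) at day 6 of induction, and to PGCLCs cultured for 3 days with gonadal somatic cells from female embryos. From these reaggregates came oocytes of secondary follicles at day 21, and metaphase II (MII) oocytes after 11 days of follicle culture and 16 hours of maturation. The counterparts from animals were primordial germ cells (PGCs) of E12.5 embryos, secondary follicle oocytes at postnatal day 8, and MII oocytes of females aged 8 weeks. Of the groups, 7 had 3 samples and 1, the day 6 PGCLCs, had 2. The culture samples came from the strain cross C57BL/6 X 129 and the animal samples from B6D2F1, so strain and route cannot be separated.

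The deposited table held 1 FPKM value per gene and group, with the separate samples not shown. There was therefore no replicate check on any difference reported here, and the read depth behind each value is unknown. Groups were compared on the scale log2(FPKM + 1) over 14242 genes, and a gene was counted as higher or lower where the ratio reached 2-fold on that scale. Ratios on this scale understate differences of genes with low values.

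Known stage genes followed the order of the groups. Nanog, a pluripotency factor, had 253 FPKM in ES cells, 120.0 in day 6 PGCLCs and 44.4 in reaggregated PGCLCs, against 0.112 in in vitro secondary follicle oocytes. Stra8, which marks entry into meiosis, had 66.7 FPKM in reaggregated PGCLCs and 63.6 in E12.5 PGCs, and was listed at 0 in day 6 PGCLCs and in in vitro secondary follicle oocytes. Dppa3, a germ cell and maternal factor, had 17.2 FPKM in ES cells, 228 in day 6 PGCLCs and 835 in in vitro MII oocytes. The germ cell RNA-binding genes Ddx4 and Dazl had 0.812 and 7.86 FPKM in ES cells, and 62.1 and 365 in reaggregated PGCLCs. Figla and Nobox, transcription factors of the growing oocyte, had 65.3 and 389 FPKM in in vitro secondary follicle oocytes, and 4.37 and 47.7 in in vitro MII oocytes. Pou5f1 was present in all 8 groups, from 197 FPKM in in vivo secondary follicle oocytes to 845 in ES cells. Sycp3, of the synaptonemal complex, had 34.0 FPKM in reaggregated PGCLCs and 115 in in vitro MII oocytes. Amh and Foxl2, both granulosa cell genes, stayed at or below 1.69 FPKM in every group.

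**Figure D1:**
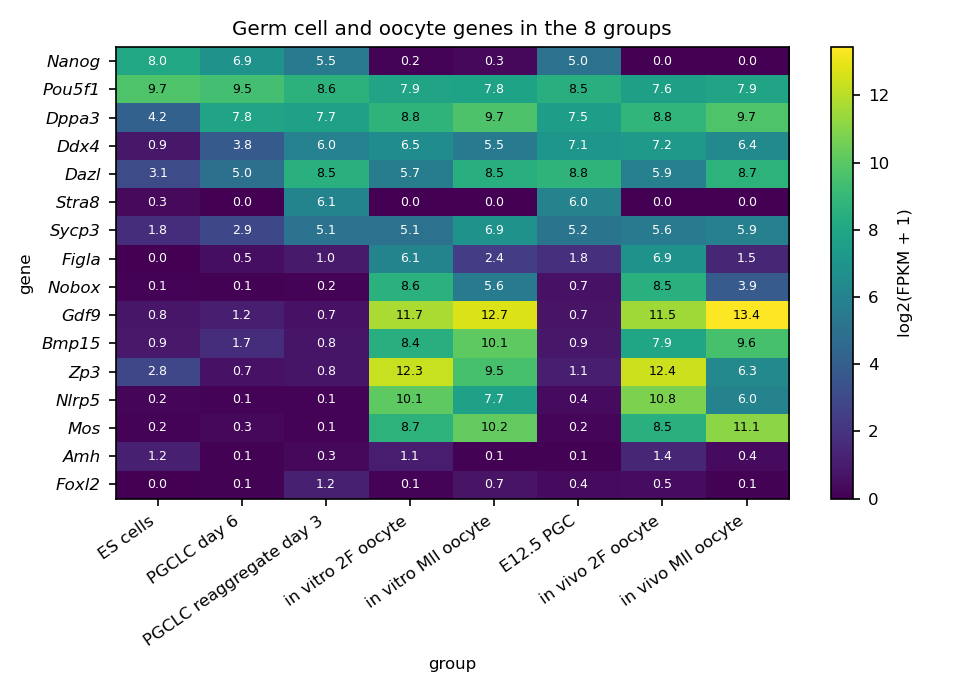
Values of 16 germ cell, oocyte and granulosa cell genes down the vertical axis, in the 8 groups along the horizontal axis, as log2(FPKM + 1), with 1 pooled value per group in each cell. Zp3 stands at 5094 FPKM in in vitro and 5544 in in vivo secondary follicle oocytes, and at 739 and 79.8 in the MII oocytes.

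Over all tested genes, each culture group was nearest to its counterpart from the animal. Spearman's rho across genes, which are not independent replicates, was 0.982 for reaggregated PGCLCs and E12.5 PGCs, 0.982 for the secondary follicle oocytes and 0.938 for the MII oocytes. The next nearest groups had 0.951, 0.757 and 0.757. A principal component analysis placed 67.6% of the variance between groups on the first component, which ran from the ES and PGC stages to the MII oocytes, and 21.7% on the second, where the secondary follicle oocytes stood apart.

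Reaggregated PGCLCs were compared with E12.5 PGCs to ask how closely germ cells made in culture match those of the embryo. Several late germ cell genes were lower in culture. Mael, of the piRNA pathway, had 28.9 against 112 FPKM, Asz1, of the same pathway, had 10.5 against 32.6 FPKM, and Sycp1, of the synaptonemal complex, had 6.19 against 23.1 FPKM. Some targets of p53 were higher (5 of 17 past 2-fold), among them Eda2r (10.3 against 2.18 FPKM), Ccng1 (23.3 against 9.73 FPKM) and Phlda3 (13.4 against 5.38 FPKM). Among genes of cholesterol synthesis 3 of 21 were past 2-fold, with the enzyme gene Msmo1 at 59.2 against 25.5 FPKM. In all, 198 genes were at least 2-fold higher and 112 lower in culture, and with a pseudocount of 5 these counts were 28 and 30.

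By gene list, 6 of 16 measured late germ cell genes were lower and 0 higher, with a median log2 ratio of -0.60, below all 10000 random lists matched on mean expression. Of 26 genes of meiotic prophase, 3 were lower (Sycp1, Syce3 and Tex15) and 0 higher, with a median of -0.40, also below all 10000 random lists. The p53 targets had 5 of 17 members higher and a median of 0.80, and the cholesterol genes 3 of 21 and 0.65, both above all 10000 random lists. Proliferation genes had a median of -0.23 (percentile 0.550) with 0 of 20 members higher and 0 lower. The naive pluripotency list had a median of 0.11 (percentile 99.1), again with 0 members past 2-fold. Genes of unfolded protein stress had a median of 0.16 (percentile 99.4) and 0 members past 2-fold.

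Markers of other gonadal cells differed in level as well. Of 18 granulosa cell genes, 3 were higher in reaggregated PGCLCs, namely Inha (4.69 against 0.839 FPKM), Amhr2 (3.20 against 0.386 FPKM) and Gja1 (1.82 against 0.0881 FPKM), and 1, Cdkn1c, was lower. The gonadal stroma list had 4 of 13 members higher and a median of 0.53, above all 10000 random lists, with Gata4 at 2.31 against 0.319 FPKM and Col3a1 at 2.42 against 0.0906 FPKM. Blood and endothelial genes had a median of -0.20 (percentile 0.350), with embryonic globin Hbb-y listed at 0 in culture and at 3.55 FPKM in E12.5 PGCs. Of 13 epiblast and mesoderm genes, 3 were lower (list median -0.22, percentile 0.155), led by Cdx2 with 2.64 FPKM in culture and a log2 ratio of -2.46.

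Among named genes with at least 10 FPKM, the highest ratios in reaggregated PGCLCs belonged to H2-Bl, a histocompatibility gene (21.8 against 0.615 FPKM), Egr1, an immediate early gene (30.1 against 6.91 FPKM), Sdc4 (88.6 against 22.5 FPKM), AA465934 (11.1 against 2.22 FPKM), Cldn3, a tight junction gene (15.2 against 3.46 FPKM), and Fam25c (16.6 against 4.09 FPKM). The lowest, after Cdx2, were Syngr1 (1.39 against 11.9 FPKM), Msx1 (5.72 against 25.8 FPKM), Etv4 (6.93 against 26.5 FPKM) and Ccnd1, a cyclin of the G1 phase (3.40 against 13.8 FPKM). The small RNA genes Scarna17 and Scarna2, each listed at 0 in 1 of these groups and at 34.9 and 25.7 FPKM in the other, are short, and their values are uncertain. Among imprinted genes, Impact was higher (19.5 against 5.74 FPKM) and Plagl1 lower (3.15 against 12.7 FPKM), and 1 of 30 was higher and 5 lower.

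Secondary follicle oocytes grown in culture were compared with those of 8-day-old females. The oocyte genes named next were within 2-fold between culture and animal. Zp3, of the egg coat, had 5094 FPKM in culture and 5544 in the animal, and the growth factor genes Gdf9 and Bmp15 had 3394 and 337 against 2936 and 239. Nlrp5, a maternal effect gene, had 1123 against 1766 FPKM and Figla 65.3 against 117 FPKM. By the 2-fold rule 248 genes were higher and 94 lower in culture, and with a pseudocount of 5 these counts were 49 and 19. Among them, 0 of 11 zona and secreted factor genes and 0 of 19 maternal effect genes were higher, with 0 and 0 lower.

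The genes that differed most at this stage were not from those lists. Higher in culture were the kinase genes Stk32a (12.6 against 0.0148 FPKM) and Stk32c (27.0 against 5.20 FPKM), Fam25c (15.6 against 0.940 FPKM), the phospholipase gene Pla2g4e (24.9 FPKM in culture, log2 ratio 3.02), the cytokine gene Il17b (26.0 against 3.01 FPKM), Tmem242 (41.4 against 6.61 FPKM), Gdpd3 (13.3 against 1.67 FPKM) and Ralgds (40.0 against 7.27 FPKM). Lower were Slc26a5, which encodes the anion transporter relative prestin (0.403 against 22.4 FPKM), the histocompatibility gene H2-Aa (2.75 against 21.5 FPKM), the chromatin protein gene Hmgn3 (2.46 against 18.2 FPKM), Trim15 (2.78 against 14.8 FPKM), St3gal5 (7.73 against 28.8 FPKM), the Wnt pathway regulator Apc (2.95 against 11.7 FPKM), Tceal8 (3.59 against 13.6 FPKM) and Wls (3.73 against 11.9 FPKM). Slc26a5 lies on chromosome 5 from 21810655 to 21865604 on the minus strand of GRCm38, the assembly also called mm10.

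Several lists had medians outside the range of random lists, by small amounts. Oocyte transcription regulators had a median log2 ratio of -0.28 (percentile 0.365), with 1 of 11 members past 2-fold, Sohlh2, which was higher (4.42 against 0.902 FPKM). Late germ cell genes had -0.19 (percentile 0.190), with Piwil2 lower (11.7 against 27.6 FPKM), and genes of maternal mRNA decay and storage -0.17 (percentile 1.02). Meiotic prophase genes had -0.12 (percentile 1.13) and nuclear genes of oxidative phosphorylation -0.09 (percentile 0.325). Pluripotency genes had 0.15 (percentile 99.6). Granulosa cell genes had a median of -0.07 (percentile 5.07), with 1 of 18 lower.

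MII oocytes, the end point of both routes, differed by more genes than the earlier stages. Their labels also give the smallest input, 99 to 134 cells in both routes, against 337 to 812 for secondary follicle oocytes. Reaggregated PGCLCs had 5300 to 15000, and no input is given for E12.5 PGCs. Whether input bears on the counts was not tested. Egg coat genes were higher in culture, with Zp3 at 739 against 79.8 FPKM, Zp2 at 483 against 37.8 FPKM and Zp1 at 383 against 35.6 FPKM. So were the maternal effect genes Npm2 (283 against 19.0 FPKM), Padi6 (329 against 79.6 FPKM) and Nlrp5 (203 against 64.5 FPKM), and respiratory chain genes such as Ndufa5 (26.8 against 0.949 FPKM), Uqcr11 (95.7 against 7.69 FPKM) and Cox4i1 (37.5 against 4.63 FPKM). Of the meiotic maturation genes the spindle checkpoint gene Bub1b (777 against 2303 FPKM) and the kinase gene Aurkc (32.2 against 179 FPKM) were lower, though Bub1b did not reach 2-fold with equal sums (-0.90). Mos, which holds the MII arrest, was within 2-fold, at 1204 against 2217 FPKM. Counted over all genes, 1772 were at least 2-fold higher and 1346 lower in culture. This split moved with the scaling, to 979 and 3112 after median centring, which put the median log2 ratio of all genes at -0.38 instead of 0.01, and to 2385 and 168 with equal sums, where it stood at 0.23. Centring shifts every log2 ratio by the same constant, also for genes at 0 in both groups, so its counts amount to a moved threshold. A pseudocount of 5 gave 642 and 844, and no pseudocount, over genes with at least 1 FPKM in both groups, 1326 and 1474.

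Energy and translation lists had positive medians. Nuclear genes of oxidative phosphorylation had 43 of 71 members higher and 1 lower, with a median of 1.31, above all 10000 random lists. Cytosolic ribosomal protein genes had 18 of 52 higher (median 0.54, above all 10000 random lists), and those of mitochondrial ribosomes and import 13 higher and 3 lower of 43 (median 0.54, percentile 99.8). Glycolysis had 7 higher and 2 lower of 16 (median 0.66, percentile 97.7), among them Pkm (40.1 against 5.97 FPKM), Aldoa and Ldhb (1724 against 379 FPKM). Cholesterol genes had 5 of 21 higher (median 0.77, percentile 99.9), led by Fdft1 (22.8 against 1.35 FPKM). These 5 medians kept their sign under quantile normalization, median centring and equal sums, but not their size. Under centring they were 0.93 for oxidative phosphorylation, 0.15 for cytosolic ribosomal proteins, 0.15 for mitochondrial ribosomes and import, 0.27 for glycolysis and 0.38 for cholesterol genes. Many ribosomal and metabolic genes have near-identical copies in the genome, so their single values are uncertain. The random lists were matched on mean expression, and not on transcript length or the step from secondary follicle to MII. Genes whose mean step over both routes was 2-fold down or more had a median of 0.53 in this comparison, so medians near that size need not be particular to a list.

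The zona and maternal effect lists stood high in culture against random lists of the same expression level, while oocyte transcription regulators (percentile 92.6) and genes of mRNA decay and storage (percentile 96.6) lay inside the range. The zona and secreted factor list had 3 of 11 members higher and 1 lower, Oosp3 (2224 against 4781 FPKM), which was within 2-fold with equal sums (-0.44). Its median was 0.32, above all 10000 random lists, and turned to -0.06 after median centring. Maternal effect genes had 9 higher and 1 lower of 19 around a median of -0.0082, which became 0.71 under quantile normalization and 0.65 with equal sums. Their mean was positive, at 0.66. Meiotic maturation genes had 2 higher, including Cdc25b (37.7 against 1.93 FPKM), and 4 lower of 20, with a median of -0.70 (percentile 33.4). The mRNAs that are stored dormant and polyadenylated at maturation had a median of -0.84 (percentile 29.4) with 0 of 14 past 2-fold. Both of these negative medians lay inside the range of random lists.

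Genes named by rank included Bfsp1, a lens filament gene (57.7 against 0.923 FPKM), Hint1 (65.2 against 1.44 FPKM), Lgals1, which encodes galectin-1 (42.9 against 0.679 FPKM), the prostaglandin D synthase gene Ptgds (42.0 against 0.887 FPKM), Cst3, for cystatin C (41.9 against 0.958 FPKM), Pinlyp (70.0 against 2.33 FPKM), Tmsb10, an actin-binding thymosin (22.0 against 0.260 FPKM), and Ergic3 (76.0 against 3.41 FPKM), all higher in culture. Lower in culture were Pdxdc1 (5.43 against 101 FPKM), Mamdc2 (0.682 against 21.9 FPKM), Tmem181c-ps (0.0803 against 13.1 FPKM), Olfr1349 (2.78 against 45.6 FPKM), Plek (0.765 against 18.9 FPKM), the growth factor gene Btc (0.145 against 11.5 FPKM), the centriole gene Cep135 (6.14 against 76.7 FPKM) and the chemokine receptor gene Cxcr3 (11.3 against 114 FPKM). Dnmt3l, a cofactor of the DNA methyltransferases, had 147 against 15.6 FPKM, and Tet3, an oxidase of methylated cytosine, 847 against 1937 FPKM, a log2 ratio within 2-fold with equal sums (-0.53). Granulosa cell genes had 3 of 18 higher (Inha, Gja1 and Inhba, the last within 2-fold after median centring, at 0.70) and a median of 0.67 (percentile 99.5), and of the stroma list Vim (14.9 against 2.24 FPKM) and Acta2 were higher.

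**Figure D2:**
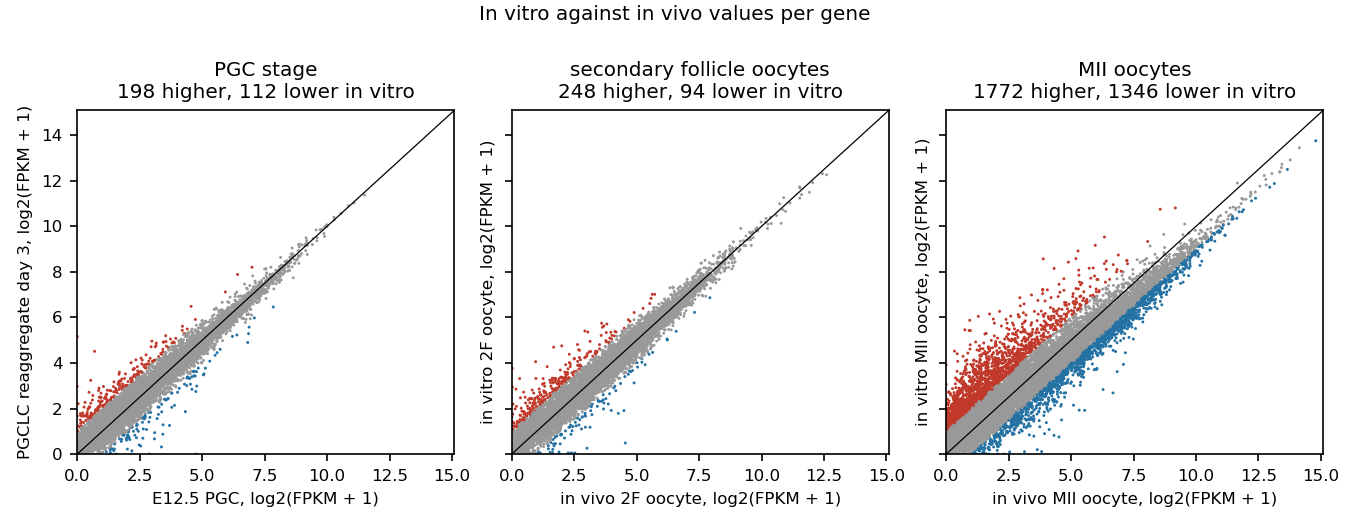
Value of each of 14242 genes in culture (vertical axis) against the animal (horizontal axis), both as log2(FPKM + 1), for the PGC stage, secondary follicle oocytes and MII oocytes. Each point is a gene with 1 pooled value per group, the line marks equal values, and colours mark genes at least 2-fold higher (red) or lower (blue) in culture, which number 198 and 112, 248 and 94, and 1772 and 1346.

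**Figure D3:**
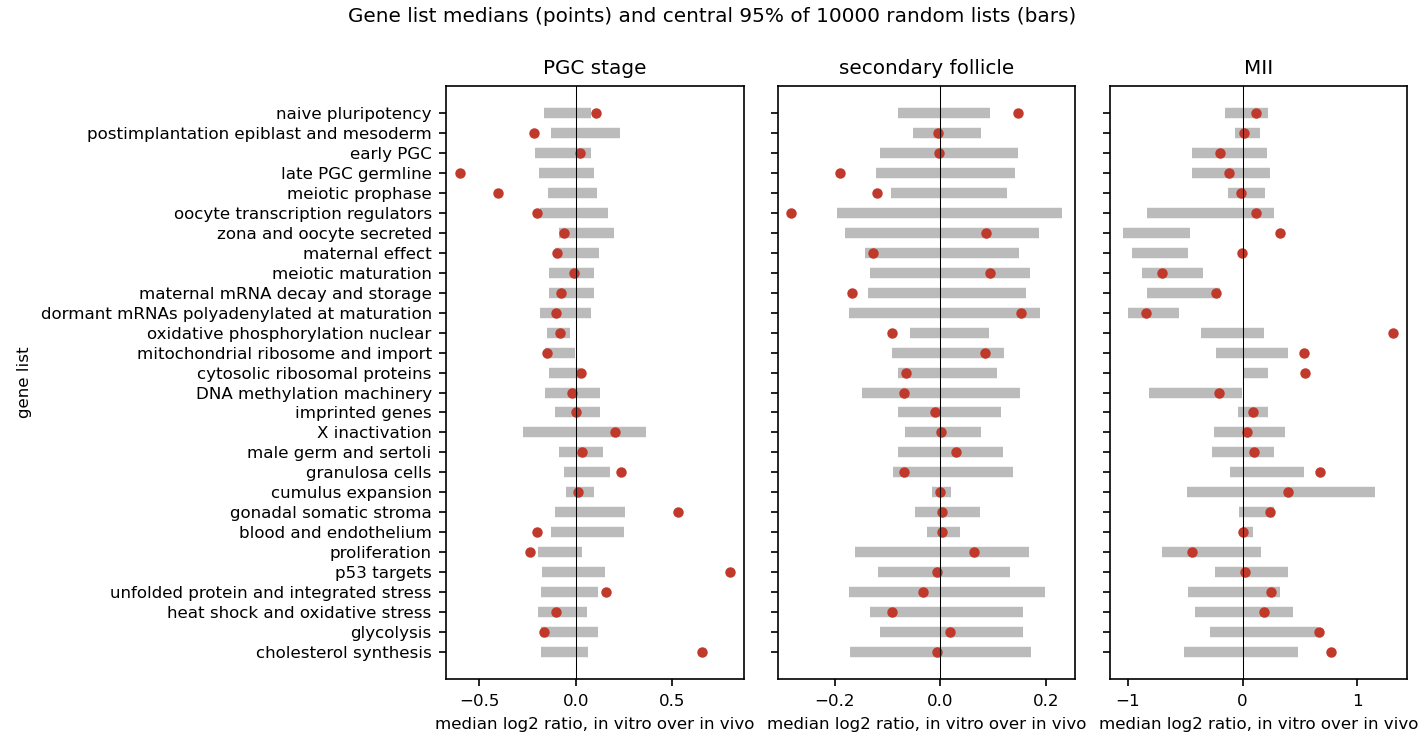
Median log2 ratio of 28 gene lists, culture over animal (horizontal axis, points), at the PGC stage, in secondary follicle oocytes and in MII oocytes, with bars for the central 95% of medians of 10000 random lists matched on mean expression. The p53 targets lie at 0.80 at the PGC stage and the nuclear oxidative phosphorylation genes at 1.31 in MII oocytes, and the horizontal scales differ between panels.

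Day 6 PGCLCs were compared with the ES cells they came from. Early germ cell genes were higher in PGCLCs, with the RNA-binding genes Dnd1 at 162 against 5.03 FPKM and Nanos3 at 35.1 against 1.85 FPKM, and Dppa3 at 228 against 17.2 FPKM. Naive pluripotency genes were lower in part, with Fgf4 at 0.0555 against 91.0 FPKM and Klf4 at 2.45 against 122 FPKM. The noncoding RNA gene H19, imprinted and on chromosome 7 from 142575529 to 142578143, had 159 against 0.0649 FPKM, and its neighbour Igf2 13.4 against 0.0573 FPKM. Several genes of DNA methylation were lower, with Uhrf1 at 7.26 against 123 FPKM, Dnmt3b at 0.864 against 21.7 FPKM and Zfp57 at 1.15 against 185 FPKM. In total 1371 genes were higher and 1712 lower, and with a pseudocount of 5 these counts were 591 and 759.

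The early PGC list had 8 of 15 members higher and 0 lower (median 1.42), and the late germ cell list 10 higher and 1 lower of 16 (median 1.70), both above all 10000 random lists. Imprinted genes had 13 higher and 7 lower of 30 (median 0.56, percentile 99.95), and the DNA methylation machinery 2 higher and 7 lower of 16 (median -0.55, percentile 1.18). Several stress genes were lower, with 10 of 17 unfolded protein and integrated stress genes lower, among them Chac1 (3.57 against 30.4 FPKM) and Trib3 (6.37 against 35.7 FPKM), and 7 of 17 p53 targets. Their medians were -1.10, below all 10000 random lists, and -0.73, percentile 0.0300. The naive pluripotency list had 3 members higher and 7 lower of 17 (median -0.51, percentile 0.455).

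Ranked by ratio, the genes higher in PGCLCs were H19, the X-linked homeobox genes Rhox6 (366 against 3.75 FPKM) and Rhox9 (407 against 4.73 FPKM), Isl2 (46.0 against 0.00820 FPKM), Plcd1 (115 against 1.51 FPKM), Lgals9 (51.3 against 0.428 FPKM), Aif1l (54.3 against 0.526 FPKM) and Sepp1 (38.5 against 0.166 FPKM). Those lower were Prps1, of nucleotide synthesis (0.334 against 143 FPKM), Fgf4, Zfp57, Pla2g1b (0.0280 against 84.5 FPKM), Laptm5 (0.0759 against 87.3 FPKM), the small heat shock gene Hspb8 (0.133 against 67.1 FPKM), Hsd17b14 (0.184 against 67.8 FPKM) and the small RNA gene Scarna10, which was listed at 0 in PGCLCs.

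Reaggregation with gonadal cells came next, comparing the PGCLCs after 3 days with those at day 6. Genes of meiotic prophase were higher after reaggregation. Stra8 had 66.7 FPKM and was listed at 0 before, the meiotic cohesin gene Rec8 had 55.1 against 13.7 FPKM and Tex12 12.7 against 1.12 FPKM. Dazl had 365 against 30.1 FPKM. Glycolysis genes were lower, with Hk2 at 2.33 against 18.5 FPKM, Pfkl at 5.39 against 33.6 FPKM and Ldha at 14.1 against 64.5 FPKM. There were 733 genes higher and 718 lower, a split that became 111 and 273 with a pseudocount of 5, and 1326 and 532 with equal sums, under which the median log2 ratio of all genes stood at 0.11 instead of -0.02.

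Of 26 meiotic prophase genes, 17 were higher and 0 lower (median 1.11), as were 10 and 0 of 16 late germ cell genes (median 1.66), both lists above all 10000 random lists. Glycolysis had 12 of 16 genes lower (median -1.74) and naive pluripotency 8 of 17, both with medians below all of them. Cholesterol genes had a median of 0.58 with 0 of 21 past 2-fold. Granulosa cell genes had 5 of 18 higher (median 0.57, percentile 99.9), with Inha at 4.69 against 0.185 FPKM. The oxidative phosphorylation list had a median of -0.07, which turned to 0.23 under quantile normalization and 0.17 with equal sums.

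Other genes with high ratios after reaggregation were Mxd4, a repressor of the Myc network (18.0 against 0.596 FPKM), the phosphatase gene Dusp9 (60.4 against 5.29 FPKM), Arhgdig (13.2 against 0.470 FPKM), Taf7l (11.8 against 0.370 FPKM), Cited1 (12.7 against 0.487 FPKM) and the small RNA gene Scarna17. Low ratios belonged to Tdgf1 (0.888 against 29.2 FPKM) and Lefty2 (2.35 against 30.5 FPKM), both of Nodal signalling, to Bcl3 (0.346 against 15.5 FPKM), the imprinted noncoding RNA Meg3 (1.93 against 30.9 FPKM), Ly6g6e (2.60 against 36.0 FPKM), Tagln2 (3.86 against 39.9 FPKM), and AF357399 and DQ267102, short RNA genes listed at 0 after reaggregation.

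Growth from the reaggregates to secondary follicle oocytes brought the largest ratios among the named genes of the steps in culture. Padi6 had 4915 against 0.444 FPKM, Zp3 5094 against 0.683 FPKM, Zp2 2885 against 0.202 FPKM, Gdf9 3394 against 0.585 FPKM and the oocyte histone gene H1foo 2036 against 0.504 FPKM. Nlrp14 (2416 against 0.595 FPKM), Npm2 (1698 against 0.247 FPKM) and Zp1 (1618 against 0.280 FPKM) completed the top 8. On the other side stood germ line and pluripotency genes of the X chromosome and beyond, with Rhox5 at 0.182 against 490.4 FPKM, Rhox9 at 0.0136 against 396 FPKM, Rhox6 at 0.126 against 278 FPKM, Utf1 at 0.124 against 391 FPKM, Ifitm1 at 0.120 against 358 FPKM and Ifitm2 at 0.375 against 295 FPKM. Crip1 and the small nucleolar RNA gene Rnu73b were listed at 0 in the oocytes, against 103 and 213 FPKM.

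All 11 zona and secreted factor genes were higher, with a median log2 ratio of 8.15, and 18 of 19 maternal effect genes with a median of 8.01. Ribosomal protein genes were lower in 49 of 52 cases (median -2.62) and oxidative phosphorylation genes in 31 of 71 (median -0.83). Meiotic prophase had 5 higher and 13 lower of 26, with Stra8 and Rec8 the lowest, and p53 targets 1 higher and 13 lower of 17. Cholesterol genes had 1 higher and 14 lower of 21. In this step 3594 genes were higher and 3755 lower, and 3138 and 4982 with equal sums, where the median log2 ratio of all genes was -0.38 instead of -0.09. With a pseudocount of 5 the larger side turned, with 2341 and 2028. The step in the animal, from E12.5 PGCs to secondary follicle oocytes, had 3466 higher and 3683 lower, and 2236 and 1977 with a pseudocount of 5. Its median over all genes was -0.34 instead of -0.09 under equal sums. Its list medians were 8.31 for zona and secreted factors, 7.61 for maternal effect genes and -2.36 for ribosomal proteins.

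The step itself was compared between routes, as the log2 step in culture minus that in the animal. Across genes the steps correlated with a Pearson r of 0.965, and the ratio of their standard deviations across genes, culture over animal, was 1.02. In both routes 3075 genes were higher, against 874.7 for independent lists, and 3138 lower, against 971, and 0 genes differed 2-fold in opposite directions. The difference of log2 steps was 1 or more for 407 genes and -1 or less for 332. This split became 84 and 53 with a pseudocount of 5, and turned to 458 and 482 with equal sums. The highest differences were those of Stk32a (3.91), the complement gene C1qb (3.35), Tmem159 (3.26), Il17b (2.94) and Pla2g4e (2.77), with the small RNA gene Scarna2 at 4.74. The lowest were those of Slc26a5 (-4.04), H2-Bl (-3.71), Egr1 (-2.72), Eif4g3 (-2.68) and H2-Aa (-2.65), with Scarna17 at -5.17.

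From secondary follicle to MII in culture, stored messages that are polyadenylated at maturation were higher. All 14 genes of that list were higher, with a median log2 ratio of 2.90 (percentile 99.9), among them Cnot7, of mRNA deadenylation (1249.7 against 24.8 FPKM), Dcp1a, of decapping (1473 against 39.3 FPKM), Btg4 (5370.1 against 269.8 FPKM) and Plat (3607 against 162 FPKM). Many maternal effect and oxidative phosphorylation genes were lower, with 11 of 19 maternal effect genes lower and 4 higher (median -1.20) and 50 of 71 oxidative phosphorylation genes lower and 2 higher (median -1.85). Because the libraries were made from poly(A) RNA, a longer tail can raise a value without more RNA, and the table cannot separate these. The zona list had a median of -0.49, which turned to 0.10 after median centring.

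Genes with the highest ratios in that step were Gtf2a1, a general transcription factor (232 against 0.543 FPKM), Spp1 (65.7 against 0.126 FPKM), Khsrp, of mRNA decay (389 against 6.00 FPKM), Nupr1 (75.9 against 0.552 FPKM), Tiparp (899 against 17.3 FPKM), Gli3, of hedgehog signalling (137 against 1.92 FPKM), and Prrg1 (62.9 against 0.393 FPKM). The lowest were Zfp707 (0.308 against 100.2 FPKM), the chaperone gene Hsph1 (3.23 against 204 FPKM), Sp110 (2.21 against 154 FPKM), Noto (4.98 against 219 FPKM), the spindle gene Tacc3 (11.2 against 376 FPKM), Ict1 (1.40 against 69.1 FPKM), Nat9 (0.776 against 50.6 FPKM) and the DNA repair gene Mgmt (42.4 FPKM before, log2 ratio -4.86). Of 6 measured cumulus expansion genes, 3 were higher at MII in culture, with Ptgs2 at 4.77 FPKM in culture and 3.45 in the animal, and Tnfaip6 at 5.91 and 4.18. The counts were 3409 higher and 4070 lower. Median centring gave 4767 and 2629, with a median log2 ratio of all genes of 0.51 instead of -0.08, and equal sums 2131 and 5619, with -0.50.

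The same step in the animal had 3988 genes higher and 4715 lower. These counts became 6089 and 2858 after median centring, with the median of all genes at 0.89 instead of -0.09, and 2170 and 6499 with equal sums, with -0.74. Dormant mRNAs had a median of 3.78, oxidative phosphorylation -3.40 with 61 of 71 lower, and maternal effect genes -2.87. Across genes the steps of both routes correlated with a Pearson r of 0.936, and 3100 genes were higher in both, against 954.6 for independent lists, and 3713 lower in both, against 1347. The standard deviation of the step across genes was 0.758 times as large in culture as in the animal. Of 3668 genes whose mean step was 2-fold up or more, 87.7% had a smaller step in culture (median 1.87 against 2.60), and of 4426 with a mean step 2-fold down or more, 81.0% (median -1.80 against -2.43).

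Gene by gene, the log2 step in culture minus that in the animal was 1 or more for 1753 genes and -1 or less for 1514. This split became 944 and 3205 after median centring and 2422 and 278 with equal sums, with the median of all genes at -0.39 and 0.24. It was 624 and 958 with a pseudocount of 5. The largest positive differences of log2 steps were those of Ptgds (5.29), Tmsb10 (4.69), Lgals1 (4.63), Cst3 (4.51), Ergic3 (4.29) and Hint1 (4.16). The largest negative ones were those of Pdxdc1 (-4.02), Cep135 (-3.68), Cxcr3 (-3.51), the metalloprotease gene Adam8 (-3.50), Btc (-3.45) and the glycosyltransferase gene Alg8 (-3.31). By list, this difference was 1 or more for 45 of 71 oxidative phosphorylation genes and -1 or less for 0 (median 1.42), and 1 or more for 19 of 52 ribosomal protein genes (median 0.51). Of 14 dormant mRNAs, 4 had -1 or less (median -0.92, percentile 7.23).

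**Figure D4:**
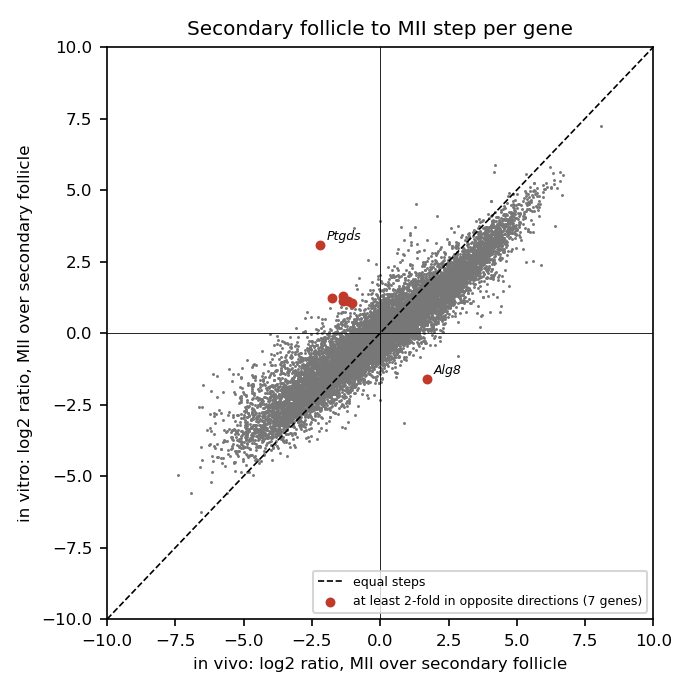
Log2 ratio of MII over secondary follicle oocytes per gene, in culture (vertical axis) against the animal (horizontal axis), for 14242 genes on the log2(FPKM + 1) scale. Points are genes, the dashed line marks equal steps, red marks the 7 genes at least 2-fold apart in opposite directions, and the cloud is flatter than the line, with a ratio of standard deviations of 0.758.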

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

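Tests chosen after the result was seen were those of scaling and of a fixed share of secondary follicle RNA for the smaller MII step, of granulosa or cumulus RNA, and of a strain difference at every stage. The tests of transcript length, of scaling for the genes higher than in both other groups, and of noise of low values were set before. All intervals below are over genes taken as independent, though genes are regulated together. They do not measure the spread between samples, which is unknown.

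For 7 genes the step from secondary follicle to MII went 2-fold one way in culture and 2-fold the other way in the animal, which is what drew attention to them. These differences were not tested, since each rests on 1 value per group, and their number depends on the processing. Genes higher in culture and lower in the animal, then the reverse, were 6 and 1 here, 54 and 20 with a pseudocount of 0.1, 2 and 0 with a pseudocount of 5, and 2 and 2 under quantile normalization. The cause was not tested. The log2 step in culture minus that in the animal was 5.29 for Ptgds, 2.98 for Dnmt3l, 2.68 for Tmsb15b2, 2.46 for Cldn25, 2.28 for Flna, 2.11 for Tuba1a and -3.31 for Alg8. Dnmt3l had 62.1 FPKM in secondary follicle oocytes and 147 in MII oocytes in culture, against 54.7 and 15.6 in the animal, and its step in culture was within 2-fold under quantile normalization (0.35) and with equal sums (0.42). Alg8 had 7.51 and 1.83 against 6.44 and 23.6. Tuba1a has close relatives with which reads can be shared, and the summed Tuba1 family was lower at MII in both routes, with log2 steps of -1.30 and -2.10. That sum was first planned as a test of shared reads and was set aside after its result was seen, since it bears on 1 of the 7 genes.

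The smaller MII step in culture was weighed first. Of the genes higher in culture than in the animal at MII, 1424 of 1772, or 80.4%, lay below their value in in vitro secondary follicle oocytes. The same share over all genes was not counted, and values were not rescaled. Over all genes, 4070 were at least 2-fold lower and 3409 higher in that step in culture, so the 80.4% alone shows no retained RNA. The tables argue against scaling as the whole cause, since the ratio of standard deviations, 0.758, reached 0.830 under quantile normalization (interval over resampled genes 0.825 to 0.836). Equal sums gave 0.803, but a single factor per group acts on that ratio only through the pseudocount, so this was not used as a test. Under equal sums the sets were drawn anew, with 2104 rising genes in place of 3668 and 6153 falling genes in place of 4426. The share with a smaller step in culture was 65.1% of these rising genes, against 87.7% before. Of the falling genes it was 85.2%, against 81.0%. In the sets as first drawn, equal sums removed most of the shortfall of the genes that are higher at MII. Their median log2 ratio of culture over animal went from -0.73 to -0.09, while that of the genes that are lower at MII went from 0.53 to 0.70. The tables argue against 1 fixed share of RNA with the secondary follicle profile, as from oocytes of that stage. Among 126 genes the percent left at MII in culture had quartiles of 8.07 and 20.4, a ratio of 2.52, with 6.69% for Padi6, 12.2% for Tle6, 14.5% for Zp3, 18.1% for Nlrp5 and 23.7% for Zp1, and a median of 12.3%. The tables also argue against transcript length as the whole cause of the gap between the medians of genes lower and higher at MII. This gap, 1.26, kept at least 87.3% of its size in each of 10 equal groups of genes by length. Length still went with the log2 ratio of culture over animal at MII, with a Spearman's rho of -0.213 across genes. The median of genes lower at MII was 0.88 in the shortest group and 0.30 in the longest. That of genes higher at MII was -0.58 and -0.80. What stays open, untested, is a share of incompletely mature oocytes, different maturation in culture and in the animal, tail-dependent capture of poly(A) RNA, female age and strain.

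The genes at least 2-fold higher in in vitro MII oocytes than in both in vitro secondary follicle oocytes and in vivo MII oocytes were weighed next. This set of genes was redefined after earlier results were seen. There were 160 of them, and 63 lower than both. Scaling between the groups cannot be told apart from a real difference for these genes. Of them, 51.2% (82 of 160, interval 43.2% to 59.2%) stayed higher than both under median centring, 85 under quantile normalization and 87 with equal sums. Centring takes the same amount off every log2 ratio of culture over animal at MII. Staying past 2-fold under it thus asks only for a larger ratio at first, and cannot decide the question. The bound set beforehand was 50%, and the demand that it be passed by more than the interval was added after the value was seen. Under all 3 scalings 49 stayed, among them Nupr1 (0.552 FPKM in in vitro secondary follicle, 75.9 in in vitro MII and 18.7 in in vivo MII oocytes), Spp1 (0.126, 65.7 and 17.6), Ptgds (4.04, 42.0 and 0.887), S100a6 (0.0179, 22.3 and 1.51) and Vim (0.411, 14.9 and 2.24). RNA from granulosa or cumulus cells, which per the labels were removed with hyaluronidase, stays open as well. Of 17 granulosa and cumulus genes with at least 1 FPKM at MII, 3, or 17.6%, were higher in culture (Gja1, Inha and Inhba) and 1, Btc, was lower, while the granulosa list as a whole had a median of 0.67 (percentile 99.5). That count covers only members of these lists, and members with low values reach 2-fold less easily on the log2(FPKM + 1) scale. The other genes among the 160 were not sorted by cell type, so the count does not measure how many could come from such cells. The wording of the granulosa and cumulus test was changed after its value was seen, to ask also for a granulosa median within the random range, which moved the verdict from excluded to open.

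Differences between culture and animal that recur in secondary follicle and MII oocytes were weighed last. The 2-fold rule was met the same way at both stages by 114 genes, 86 higher against 30.9 for independent lists and 28 lower against 8.88, and in opposite ways by 16. They include Hmgn3 (2.46 against 18.2 FPKM in secondary follicle and 14.3 against 136 in MII oocytes), Slc26a5 (0.403 against 22.4 and 2.95 against 17.1), Ralgds (40.0 against 7.27 and 11.0 against 1.43) and Ada (52.7 against 11.1 and 6.90 against 0.839). Noise of low values is argued against, since with at least 10 FPKM in the higher group at both stages, which leaves low values in the other group, 29 genes recurred against 9.48, a ratio of 3.06. A strain difference present at every stage could be checked only for the 73 of the 114 genes with at least 1 FPKM in reaggregated PGCLCs or E12.5 PGCs. It is argued against as the cause for these 73 as a set, since 37 of them, 50.7% (interval 38.7% to 62.6%), had the same sign in PGCs, against 54.3% of other genes. For the rest of the 114 it was not checked. That count takes in genes with almost no difference in PGCs. Of those past 2-fold there, 6 went the same way (Fam25c, Fxyd6, Bcat2, Tead2, Prdm1 and Tuba3b) and 2 the opposite way (C1qb and Tmem51), so a strain difference stays open for single genes. The bound of that test was reworded after its value was seen, with the same verdict. A strain difference limited to oocytes, the age of the females and the culture itself stay open and untested.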

How the results depend on the processing

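The alternatives with equal sums and without a pseudocount, those without ribosomal and respiratory chain genes and the similarity over genes with 1 FPKM in all 8 groups were chosen after seeing the data. Counts are given as genes higher, then lower, in the first group named. Of 198 counts under the alternatives, 144 stayed within 1.5 times the count reported, and 54 moved further. A small pseudocount lets low values reach 2-fold and a large one prevents it. Median centring shifts all log2 ratios of a comparison by the same constant, and so moves the threshold. For quantile normalization and equal sums the cause was not tested. The 1-value design allowed no count of other splits of the samples.

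With a pseudocount of 5, reaggregated PGCLCs against E12.5 PGCs had 28 and 30, in vitro against in vivo secondary follicle oocytes 49 and 19, in vitro against in vivo MII oocytes 642 and 844, day 6 PGCLCs against ES cells 591 and 759, and reaggregated against day 6 PGCLCs 111 and 273. The secondary follicle step had 2341 and 2028 in culture and 2236 and 1977 in the animal, and the MII step 2583 and 2498 in culture and 3216 and 3069 in the animal. The differences of steps had 84 and 53 for the secondary follicle step and 624 and 958 for the MII step. The larger side changed in all 11 comparisons except the secondary follicle oocytes of culture against animal, day 6 PGCLCs against ES cells, and the difference of secondary follicle steps.

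With a pseudocount of 0.1, the 3 comparisons of culture with animal had 673 and 354 at the PGC stage, 708 and 322 in secondary follicle oocytes, and 3695 higher in MII oocytes. Day 6 PGCLCs against ES cells had 2253 higher, and reaggregated against day 6 PGCLCs 1741 and 1258. The differences of steps had 992 and 967 for the secondary follicle step and 3551 higher for the MII step. With no pseudocount, only genes with at least 1 FPKM in the groups compared are used, and so fewer genes. The secondary follicle step then had 2265 and 2466 in culture and 2168 and 2413 in the animal, and its difference 266 and 221. The larger side turned in in vitro against in vivo MII oocytes (1326 and 1474) and in reaggregated against day 6 PGCLCs (596 and 753). It also turned in the MII step in culture (3047 and 2996), in the animal (3420 and 2465) and in their difference (1207 and 1363).

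After median centring, in vitro against in vivo MII oocytes had 979 and 3112, the MII step 2629 lower in culture and 6089 and 2858 in the animal, and its difference 944 and 3205. With equal sums, in vitro against in vivo MII oocytes had 168 lower, the MII step 2131 higher in culture and 2170 in the animal, its difference 278 lower, reaggregated PGCLCs against E12.5 PGCs 314 higher, and reaggregated against day 6 PGCLCs 1326 higher. Quantile normalization gave 1161 and 805 for in vitro against in vivo MII oocytes and 973 lower for the difference of MII steps.

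Of 2123 list medians, 15 were counted as reversed, 187 moved by a factor of more than 1.5, and 1921 were counted as neither. A change of sign counted as reversed only where the list lay outside the range of random lists in the main setting. Changes of sign in the other lists were not counted. After median centring, zona and secreted factor genes reversed in MII oocytes of culture against animal (-0.064), in the MII step in culture (0.10), in that step in the animal (0.19) and in the difference of those steps (-0.20). In that difference maternal effect genes (-0.26), genes of maternal mRNA decay and storage (-0.24) and gonadal stroma genes (-0.10) reversed as well. Also under centring, mRNA decay and storage genes reversed in the MII step in the animal (0.74) and ribosomal protein genes in reaggregated PGCLCs against E12.5 PGCs (-0.0094). Under quantile normalization, maternal effect genes reversed in MII oocytes of culture against animal (0.71), mRNA decay and storage genes in the MII step in the animal (0.012), and oxidative phosphorylation genes in reaggregated against day 6 PGCLCs (0.23). Equal sums reversed maternal effect genes in MII oocytes of culture against animal (0.65) and oxidative phosphorylation genes in reaggregated against day 6 PGCLCs (0.17), and a filter of 5 FPKM reversed gonadal stroma genes in the secondary follicle step in culture (0.0078).

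Of 7598 values of named genes, 354 no longer reached 2-fold, 7244 still did, and 0 reversed. All 39 values of similarity and step agreement under the alternatives moved by less than 0.1. Similarity between groups rests on ranks, so a pseudocount of 0.1 or 5 and quantile normalization could not move it. Similarity to the next nearest group was not counted, and in the oocyte groups it moved further. For in vitro secondary follicle oocytes it went from 0.757 to 0.867 without the filter. Over genes with at least 1 FPKM in all 8 groups, reaggregated PGCLCs replaced in vitro MII oocytes as next nearest to these oocytes, at 0.522. For in vitro MII oocytes the next nearest group stayed the same, at 0.480. Leaving out the filter changed 3 counts, to 1754 higher for the difference of MII steps and to 409 higher and 336 lower for that of secondary follicle steps. No paired analysis was possible because the table holds 1 value per group and its columns carry no replicate numbers. Not run for the same reason were a fit of only 2 groups, array weights, adjusted p alone, a replicate block, leaving out samples, camera with estimated correlation, and fry. Depth is not given in the sources used here, so its limit on low values cannot be stated.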

Other observations

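No further tests were run for the values in this part, and the gene families in it were chosen after the data were seen. Genes on the X chromosome, which female cells can express from 1 or 2 copies, had a median in ES cells of 12.0 FPKM among those with at least 1 FPKM, against 11.4 for autosomal genes, a ratio of 1.05. The ratio was 0.714 in day 6 PGCLCs, 0.751 in reaggregated PGCLCs and 0.760 in E12.5 PGCs. In culture it was 0.597 in secondary follicle and 0.716 in MII oocytes, against 0.620 and 0.677 in the animal.

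Some gene families of the germ line differed between stages. The X-linked Rhox homeobox genes, 16 in all, summed to 1201 FPKM in reaggregated PGCLCs and 8.79 in in vitro secondary follicle oocytes, with 13 lower and 1 higher in the oocytes, and to 985 and 17.8 FPKM in E12.5 PGCs and in vivo secondary follicle oocytes. The Oog, Nlrp4, Nlrp9 and Oas1 genes, expressed in oocytes, had 18 of 20 members higher in secondary follicle oocytes in each route and summed to 8.58 FPKM in reaggregated PGCLCs and 3890.0 in in vitro secondary follicle oocytes. Of 7 Khdc1 and Obox genes, 6 were higher in secondary follicle oocytes in each route. Members of these families are close copies, so single values within them are uncertain.

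Sums of FPKM differed between groups, from 268720 in reaggregated PGCLCs to 616260 in in vitro and 975407 in in vivo MII oocytes, against 349451 and 349772 in the secondary follicle oocytes. The gene with the highest value at MII was Zbed3, which encodes a protein of the subcortical maternal complex, with 13848 FPKM in culture and 28436 in the animal. Some genes with many processed copies stood near 0 throughout, such as Gapdh, at most 0.757 FPKM, and Ppia, at most 2.61. Ndufc1, of the respiratory chain, was listed at 0 in in vivo MII oocytes and had more than 5 FPKM in each of the other 7 groups.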
